A study of Mus musculus with 6 samples.

How the data were processed

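Single-cell RNA was measured in 6 libraries of mouse back skin, 3 titled Mat2a LOF and 3 titled Control. Group and replicate number were taken from the sample titles. The series description says that the tissue is wound margin from knockout and wild-type mice, 3 of each, so each library was treated as 1 animal; its sex, age, day of wounding and the allele used are not given in the sources used here. The label fields for genotype and treatment hold library terms in place of a genotype or a treatment and were not used. Cells were captured with droplet 3′ chemistry and sequenced as paired ends, per the labels' protocols. The deposited values are whole-number UMI counts per gene and barcode, not normalised, made with Cell Ranger 8.0.0 and the mouse build mm10, per the submitters' processing notes. The annotation release and the cell-calling settings are not given in the sources used here. The files pair each Ensembl gene ID with a symbol, and 32236 of the 34290 IDs were found in the GENCODE M21 annotation of the same build; 43 symbols belong to more than 1 ID and were kept apart by ID.

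The files held 70923 barcodes. The lowest UMI total of a barcode was 500 to 503 in each library, so barcodes below that number had already been left out. Barcodes with at least 500 UMIs, at least 300 genes and at most 15% of UMIs from mitochondrially encoded genes were kept, which left 69248. Doublets were scored per library with the Scrublet function of scanpy, and the barcodes with the highest scores were removed at 0.8% per 1000 cells of the library, which took 8.56% to 10.3% of each library and left 62815 cells. No correction for free RNA was applied to the counts. Every pair of libraries differed by more than counting noise (chi-square per degree of freedom at least 120.516), so no library was counted as a repeat of another.

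Cells of all libraries were clustered together in Python 3.11.15 with scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components, 15 neighbours and Leiden resolution 1 were used, with no batch integration. A cluster took the name of the marker list with the highest mean z-score if at least 3 of its markers were detected (in at least 20% of its cells), its top 10 genes by fold over the other clusters did not hold more markers of another list, and it did not combine low UMI counts with no marker among those genes. Top genes had at least 50 CPM and were detected in at least 25% of the cluster. The names are therefore likenesses (fibroblast-like and so on), rebuilt from markers, and are written without the suffix. Clusters that failed these conditions stayed unnamed and entered no class.

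The libraries are the replicates. For all cells together and for each of the 6 named classes with the most cells and at least 50 cells in every library, UMI counts were summed per library and tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, the default filter on low counts, and the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene is called where it passed that threshold. Fold changes are log2 values of Mat2a LOF over control. Gene lists fixed beforehand were tested as sets within each comparison with camera in limma 3.58.1 (correlation between genes preset to 0.01, Benjamini-Hochberg over the lists with at least 5 tested members), beside the number of members called over all genes and the number called when p-values were adjusted over the list alone. camera with an estimated correlation and fry, whose p tests whether the members move one way on balance, were alternatives. Shares of cells per class were compared by exact two-sided permutation of the 3 and 3 libraries, whose smallest possible p is 0.1. For each gene in a class, the ratio of its CPM there to that in the named class where it is highest was computed, as a measure of how far free RNA of other cells can set its counts; a ratio under 10% is stated where such a gene is named.

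The rule for named genes took Mat2a everywhere; per class, the 8 called genes with the largest fold change each way among those whose 3 LOF values all lay on the same side of the 3 control values, with at least 20 CPM and a class ratio of at least 10%; up to 4 called members per list by smallest p; and 5 each way for all cells together. Predicted genes, RIKEN clones and mitochondrial, haemoglobin, immunoglobulin and T-cell receptor genes were passed over. In a class with no called gene, the 4 each way with the smallest p were named as values. Group assignment, tests, marker and gene lists, filters, the rule for named genes and the alternatives other than those named here as added were fixed before the data were examined. Alternatives were DESeq2 1.42.0 (its size factors in edgeR, and its own Wald test), no filter on low counts, the replicate number as a block, no doublet removal, a stricter cell filter (500 genes and 10%), Leiden resolution 0.5, leaving out genes with a class ratio under 10%, other scales and tests for the shares (a centred log-ratio with 0.5 added, and edgeR on cell counts) and leaving out each library in turn. With 1 library left out, the arm of 2 was fitted with the spread pooled over both arms. Added after seeing the data were sex as a covariate and the male libraries alone (sex read from Xist and Y-linked genes), the return to their closest class of clusters left unnamed only because of markers of another class among their top genes, fibroblasts without a cluster of dividing cells, and a test of whether classes changed differently (the interaction of class and group, with the library as a block).

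The gene tests, the list tests and the interaction of fibroblasts and neutrophils were tested on simulated data drawn from the real means, spreads and library sizes with 200 changed genes. With 19115 genes simulated as in fibroblasts, edgeR recovered 68% of genes changed 4-fold and 12% of those changed 2-fold, and 8.33% of its calls were unchanged genes; DESeq2 recovered 79% and 45%, and 30.5% of its calls were unchanged genes. The matching shares for edgeR were 90% and 23% in macrophages (14811 genes), 68% and 7.07% in neutrophils (12466 genes), 72% and 9% in keratinocytes (14058 genes), 78.8% and 24% in endothelial cells (12039 genes), 87% and 16.3% in lymphocytes (9711 genes), and 57% and 3% in all cells together (21940 genes). For the interaction of fibroblasts and neutrophils (12192 genes), 51% of genes changed 4-fold were recovered. The simulated shares belong to 200 changed genes and need not hold where more genes change. camera called a simulated shifted list in every comparison, and at most 1 of 27 lists that had not been shifted. Simulated genes were drawn independently, so this does not show how often camera calls unshifted lists of correlated genes. In another split of the real libraries into 3 and 3, it called 18 lists in all cells. With an estimated correlation camera missed the simulated shifted list in keratinocytes (unadjusted p = 0.00304) and in lymphocytes (unadjusted p = 0.00237). The ribosomal list was made by a pattern of symbols, and 10 of its 101 genes are S6 kinase genes. Figures were drawn with matplotlib 3.10.9.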

Results

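The series asks how the cells of a skin wound margin differ when Mat2a is altered. Across the 6 libraries, 62815 cells were kept, 9798, 11586 and 11345 from Mat2a LOF 1 to 3 and 10097, 9783 and 10206 from Control 1 to 3. The median UMI count per kept cell was 6336, 8028 and 7639 in LOF and 8472, 10689 and 6258.5 in control, and the median number of genes 2056, 2681 and 1815 against 2887, 3492 and 2275.5. The median percent of mitochondrially encoded UMIs was 0.917, 0.968 and 0.655 in LOF and 1.03, 1.32 and 1.10 in control, lower in each LOF library. Xist and Ddx3y counts place LOF 1 and Control 1 as female and the other 4 libraries as male, so each group holds 1 female and 2 males. Values from the males alone stand beside the pooled counts. The females, 1 per group, give no value of their own.

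Mat2a encodes the catalytic enzyme that makes S-adenosylmethionine from methionine. With all 6 libraries, edgeR called its RNA neither lower nor higher in all cells together or in the 6 classes tested. Over all cells it was 136, 130 and 112 CPM in LOF 1, 2 and 3 and 157, 147 and 149 CPM in Control 1, 2 and 3, lower in each LOF library than in each control (log2 fold change -0.26, SE 0.14, edgeR adjusted p = 0.232, -0.35 in the males). In fibroblasts it was level at 145 ± 1.32 CPM (mean ± SD) in LOF and 142 ± 7.47 CPM in control, a log2 fold change of 0.03. In macrophages it was 159 ± 29.9 against 223 ± 21.4 CPM (log2 fold change -0.48, SE 0.17, edgeR adjusted p = 0.110), lower in each LOF library. It was called lower without LOF 1 (-0.66, edgeR adjusted p = 0.0151) and in the males alone (-0.58, 0.0475), and over all alternatives its adjusted p ran from 0.0151 to 0.293. The log2 fold change was -0.12 in neutrophils, -0.03 in keratinocytes, -0.06 in endothelial cells and -0.0049 in lymphocytes. Among the classes outside the 6 tested across genes, pericytes and smooth muscle had 120 ± 31.1 CPM in LOF and 200 ± 20.4 CPM in control (log2 ratio -0.77, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The labels do not say which part of the gene was altered or in which cells, and a 3′ tag outside a deleted part checks nothing, so these counts neither verify nor contradict the group labels.

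**Figure D1:**
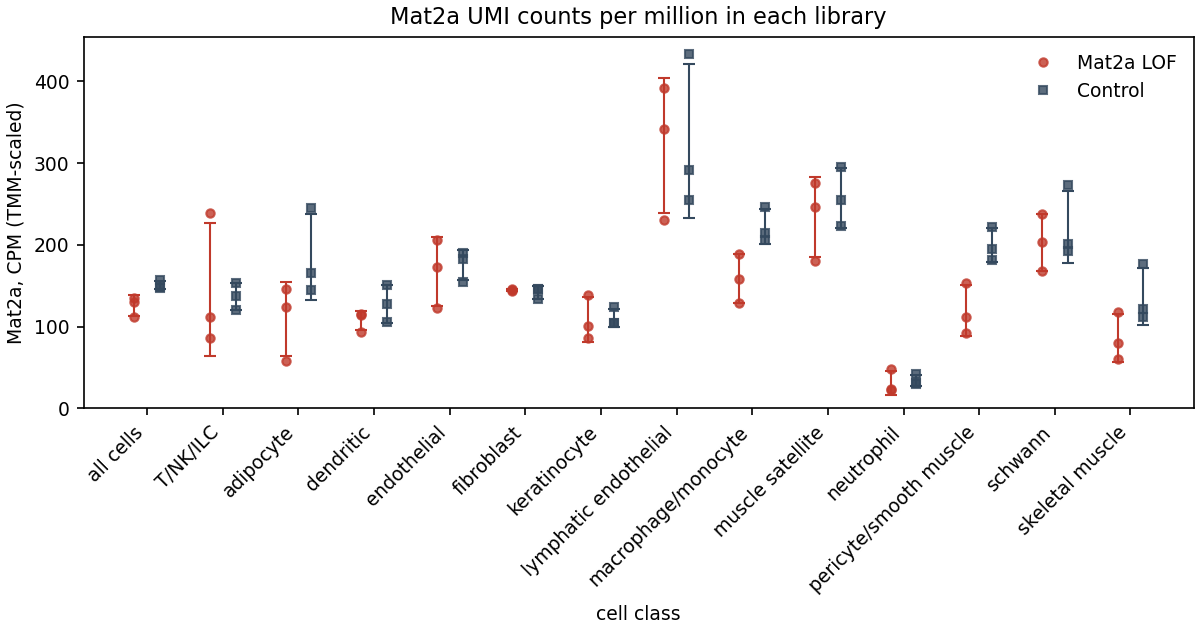
Mat2a in CPM (vertical axis, TMM-scaled) for all cells and each cell class, with 1 point per library (red circles Mat2a LOF, dark squares control) and bars for the mean and SD of 3 libraries. Fibroblasts lie at 145 ± 1.32 CPM in LOF and 142 ± 7.47 CPM in control, and macrophages at 159 ± 29.9 and 223 ± 21.4 CPM.

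The kept cells fell into 13 named classes, among them fibroblast-like, neutrophil-like, macrophage- or monocyte-like, keratinocyte-like, endothelial-like and T, NK or innate lymphoid-like cells, written from here as fibroblasts, neutrophils, macrophages, keratinocytes, endothelial cells and lymphocytes. No class share passed its test. Fibroblasts made up 14.1 ± 8.02% of LOF cells and 31.2 ± 6.30% of control cells, and endothelial cells 3.09 ± 2.25% and 6.01 ± 1.52%. Schwann cells were 1.32 ± 0.752% and 0.618 ± 0.0123%. In these 3 classes the groups did not overlap, where chance gives 1.3 of 13 classes. The exact two-sided permutation p was 0.1 for each, the smallest possible, and 0.433 after Benjamini-Hochberg adjustment. Neutrophils were 34.4 ± 21.3% against 19.6 ± 8.32%, with 58.4% in LOF 3, macrophages 16.3 ± 3.69% against 13.6 ± 2.25%, keratinocytes 9.17 ± 4.37% against 4.15 ± 1.78% and lymphocytes 3.43 ± 3.68% against 1.88 ± 0.150%, with 7.6% in LOF 2. Clusters left unnamed held 11.9 ± 4.32% and 16 ± 2.09% of cells. The largest, cluster 6, held 3.44% and 6.88%, and cluster 11, closest to fibroblasts, 2.16% and 4.95%. Cluster 6 had low UMI counts (0.159 of the library median) and was led by Stab1, Mrc1 and Cd163, genes of the reparative macrophage list. The macrophage shares above leave its cells out.

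**Figure D2:**
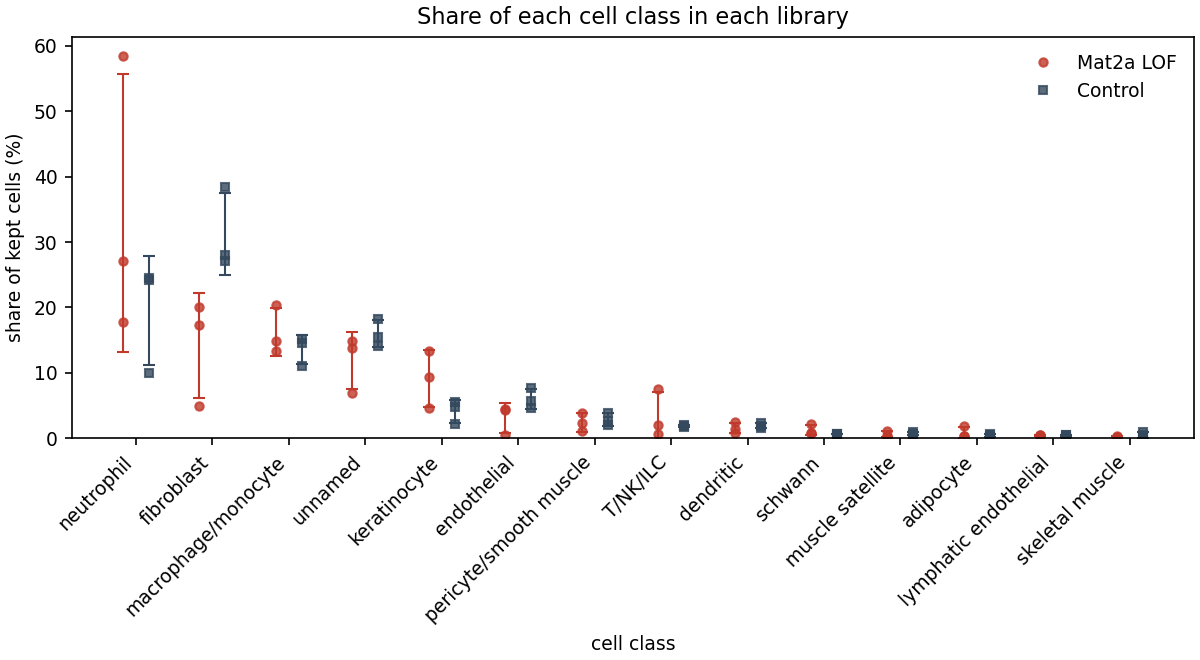
Share of kept cells (vertical axis, percent) in each class, with 1 point per library (red circles Mat2a LOF, dark squares control) and bars for the mean and SD of 3 libraries. Fibroblasts take 14.1 ± 8.02% of LOF cells and 31.2 ± 6.30% of control cells, and neutrophils reach 58.4% in 1 LOF library.

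All cells together mix expression with the shares of classes. Sums per class likewise mix expression with the shares of the clusters within the class. edgeR called 1869 of 21940 genes, 620 higher and 1249 lower (456 in the males alone, 317 of them shared). Among called genes with at least 20 CPM on average and predicted genes passed over, Ngp, a neutrophil granule gene (log2 fold change 5.67), Chil3 (4.47), the stefin Stfa2 (4.36), U90926 (4.23) and the acute-phase gene Saa1 (3.67) had the largest rises. C1qtnf3 (-4.75), the growth factor Ptn (-4.65), Prss35 (-4.36), the collagen gene Col6a6 (-4.06) and Pamr1 (-3.97) had the largest falls, with edgeR adjusted p from 0.0189 to 0.0454 over these genes, and each separated the 3 LOF from the 3 control libraries. Of 50 matrix genes 14 fell and none rose (31 down and 1 up adjusted over the list alone, camera adjusted p = 8.6e-11 and 0.760 with an estimated correlation), and of 23 glycolysis genes 12 rose and none fell (18 and 1 adjusted over the list alone, camera adjusted p = 7.6e-08 and 0.703 with an estimated correlation). Of 25 hypoxia targets 7 rose and none fell (15 and 0 adjusted over the list alone, camera adjusted p = 3.3e-08 and 0.565 with an estimated correlation). The count was 3575 without LOF 1, 601 without LOF 3, 73 without Control 3, and 0 without LOF 2, Control 1 or Control 2, where 7002, 5093 and 4296 genes had an unadjusted edgeR p under 0.05.

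Fibroblasts had the most called genes of the 6 classes with all 6 libraries, but fewer than neutrophils without Control 1. LOF fibroblasts carried more RNA for Lcn2, Cxcl5 and Csf3 and less for Eln, Ptn and Igf1. Cluster 5, led by Ptn, Prss35, H19, C1qtnf3 and Mest, held 32.8 ± 6.87% (mean ± SD) of control and 0.648 ± 1.12% of LOF fibroblasts. Cluster 23, led by Cxcl5, Il11, Csf2, Serpinb2 and Il6, held 1.71%, 24.9% and 18.8% of fibroblasts in LOF 1, 2 and 3 and 0.0236 ± 0.0408% in control. Cluster 26, led by Grem1 and Mmp3, held 0.648%, 15.7% and 15.4% in LOF 1, 2 and 3 and 0.204 ± 0.267% in control. LOF 1 had 58.9% of its fibroblasts in cluster 10, led by Prokr2 and Tafa2, against 5.67% and 4.74% in LOF 2 and 3 and 10.9 ± 1.34% in control. Fold changes of the fibroblast sums include these shifts between clusters, above all for genes that lead clusters 5 and 23. Changes within a single cluster were not tested. edgeR called 4471 of 19115 genes, 2312 higher and 2159 lower, of which 1264 and 1167 changed at least 2-fold (7251 in the males alone, 3950 of them shared). In 47.3% of tested genes the groups did not overlap, where chance gives 10%. The count was 9095 without LOF 1, 1101 without LOF 2, 1182 without LOF 3, 25 without Control 1, 34 without Control 2 and 607 without Control 3, and of the 111 called genes that the naming rule picks, 111, 70, 72, 3, 3 and 57 were still called.

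Lcn2, which binds bacterial siderophores, rose in fibroblasts from 81.6 ± 71.7 to 2464 ± 1593 CPM (log2 fold change 4.92, SE 1.15, edgeR adjusted p = 0.0302), and the neutrophil growth factor Csf3 from 21.9 ± 10.6 to 511 ± 286 CPM (4.55, SE 0.65, edgeR adjusted p = 0.0134). Serpinb2, an inhibitor of plasminogen activators, rose by 4.45 and the neutrophil chemokine Cxcl5 by 3.99 on the log2 scale, with U90926 (5.70), Serpina3m (3.95), the B-cell chemokine Cxcl13 (3.58) and Csf2 (3.52). Of 35 NF-kB targets, 15 rose, none fell and 20 were not called (17 up and 1 down adjusted over the list alone, median log2 fold change 1.05). camera called the list (adjusted p = 9.4e-06 and 0.521 with an estimated correlation). Its members include Sod2 (2.92), Ptgs2, the inducible prostaglandin synthase (1.78), and Nfkb2 (1.24). Of 66 secretory genes associated with senescence, 20 rose, 8 fell and 38 were not called (27 and 11 adjusted over the list alone, camera adjusted p = 0.00568 and 0.521 with an estimated correlation). The epidermal growth factor receptor ligand Ereg rose by 1.83, while Igfbp5 fell by 1.5. Of 23 genes of inflammatory macrophages, 5 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00195 and 0.549 with an estimated correlation). Il6 rose from 209 ± 87.1 to 1221 ± 521 CPM (log2 fold change 2.55) and Nos2 by 2.69, while the interferon-induced chemokine Cxcl9 fell by 1.75. With genes under 10% of their CPM in the highest class left out, camera no longer called this list (adjusted p = 0.0924, 2.5e-05 to 0.549 over its alternatives). Its median log2 fold change was then 1.52, with fewer genes tested.

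Of 48 proliferation genes in fibroblasts, 45 rose and none fell (48 and 0 adjusted over the list alone, median log2 fold change 1.13, camera adjusted p = 2.0e-17 and 0.521 with an estimated correlation). They include the replication helicase gene Mcm5 (1.76), thymidylate synthase Tyms (1.47), the mitotic kinase Cdk1 (1.37) and the spindle motor Kif11 (1.14). Cluster 20, led by cell-cycle genes, held 10.6% of LOF and 3.98% of control fibroblasts. Without it, an alternative chosen after seeing the data, 18 of the 48 rose and the median was 0.68. Of 98 genes with ribosomal symbols, 48 rose and 1 fell (70 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 5.1e-15 and 0.521 with an estimated correlation), among them Rpl18 (0.94), Rps6 (0.85) and Rpl37 (0.83). The 101 symbols matched include 10 S6 kinase genes, which are not ribosomal, and of these Rps6ka1 rose (0.78) and Rps6ka5 is the gene that fell (-0.48). Of 23 glycolysis genes, 14 rose and none fell (16 and 2 adjusted over the list alone, median 0.87, camera adjusted p = 9.4e-06 and 0.521 with an estimated correlation). Lactate dehydrogenase Ldha rose from 172 ± 37.2 to 500 ± 103 CPM (1.54), with the monocarboxylate carrier Slc16a1 (1.72) and pyruvate kinase Pkm (1.53). Gapdh (1.21) had only 0.075 of its CPM in its highest class.

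Of 25 hypoxia targets in fibroblasts, 9 rose and none fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000832 and 0.521 with an estimated correlation), including the glucose carrier Slc2a1 (1.57), the cytokine Mif (1.46) and Ddit4 (1.06). Of 31 ATF4 amino acid response genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.00568 and 0.521 with an estimated correlation). Asparagine synthetase Asns (1.16) and Sesn2 (1.05) rose, and the stress factor Atf3 fell from 631 ± 42.4 to 217 ± 24.2 CPM (-1.54). Of 74 nuclear genes of oxidative phosphorylation, 11 rose, none passed when adjusted over the list alone, and the median was 0.25 (camera adjusted p = 4.1e-05 and 0.587 with an estimated correlation). Cytochrome c, Cycs, rose by 1.12. Of the 13 mitochondrially encoded genes, mt-Nd6 fell (-0.57) and 12 were not called (0 and 0 adjusted over the list alone, camera adjusted p = 0.00993 and 0.587 with an estimated correlation). The median percent of mitochondrially encoded UMIs per fibroblast was 1.02, 0.773 and 0.756 in LOF and 1.07, 1.23 and 1.16 in control. Without LOF 1, camera no longer called the hypoxia targets (adjusted p = 0.0794) or the ATF4 genes (0.0503).

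Of 50 matrix genes in fibroblasts, 9 fell, 5 rose and 36 were not called (10 and 5 adjusted over the list alone, median log2 fold change -0.90, camera adjusted p = 0.000267 and 0.587 with an estimated correlation). Elastin, Eln, fell from 507 ± 201 to 71.0 ± 12.5 CPM (-2.84), the small proteoglycan Aspn from 1919 ± 232 to 196 ± 211 CPM (-3.29), and Col15a1 (-1.88), Fbln5, which helps assemble elastic fibres (-1.34), and Thbs2 (-1.22) fell too. Among called fibroblast genes with at least 20 CPM and 10% of their CPM in the highest class, predicted genes passed over, the largest falls were in Ptn, from 510 ± 243 to 5.44 ± 6.65 CPM (-6.54, SE 1.10, edgeR adjusted p = 0.0168), the Notch-like Dlk1 (-5.95), the imprinted gene Mest (-4.43), Prss35 (-3.75), Col6a6 (-3.66), Pamr1 (-3.54) and Ppp2r2b (-3.31). Of 22 contractile genes, 6 fell and 3 rose (8 and 4 adjusted over the list alone, camera adjusted p = 0.103). The collagen-binding integrin Itga11 fell by 2.47 and the actin crosslinker Actn1 rose by 1.03, while the falls of Tagln (-1.95) and Myl9 (-1.79) are in genes at 0.039 and 0.029 of their CPM in the highest class. Of 30 hair follicle genes, 8 fell and 4 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.358), with the Wnt-pathway genes Lgr5 (-2.48), Axin2 (-1.44) and Tcf7l1 (-1.07) lower. Of 25 genes of reparative macrophages, 4 fell and 2 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.579). The growth factor Igf1 fell from 561 ± 131 to 138 ± 47.9 CPM (-2.02) and Tgfb1 rose by 0.83.

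Of 47 interferon response genes in fibroblasts, 5 fell and none rose (2 and 0 adjusted over the list alone, median log2 fold change -0.39, camera adjusted p = 0.0114 and 0.702 with an estimated correlation). The transcription factor Irf1 fell from 145 ± 6.76 to 59.9 ± 11.5 CPM (-1.28), with Ifi27l2a (-1.53), Cmpk2 (-1.33) and Ifit3b (-1.27). Of 29 genes induced by dissociation or as immediate early genes, 7 fell and 3 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.0456 and 0.521 with an estimated correlation). The chaperone genes Dnajb1 (-1.17) and Hsph1 (-0.97) fell and Ier3 rose (1.05). Without LOF 1 or Control 3, camera no longer called the interferon list (adjusted p = 0.367 and 0.126), and without LOF 1, Control 1 or Control 3 it no longer called the dissociation list (0.0981, 0.0514 and 0.0879).

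Of 22 genes of the methionine cycle in fibroblasts, 6 rose and 2 fell (9 and 2 adjusted over the list alone, median log2 fold change 0.31, camera adjusted p = 0.0550 and 0.546 with an estimated correlation). The list passed by fry (adjusted p = 0.0436), by camera with genes under 10% of their highest class left out (0.0442) and by camera with sex as a covariate, chosen after seeing the data (0.0409), in a range of 0.0409 to 0.546 over its alternatives. Ahcy, which clears S-adenosylhomocysteine, rose by 1.48, cystathionine gamma-lyase Cth by 1.80, and the amino acid carrier genes Slc7a5 and Slc3a2 by 0.99 and 0.66. Both carrier genes are also in the ATF4 list. Of 14 polyamine genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.312, fry adjusted p = 0.0436). Ornithine decarboxylase Odc1 rose from 111 ± 13.3 to 456 ± 245 CPM (2.04), spermidine synthase Srm rose by 0.88 and Sat2 fell by 1.01. Of 38 methyltransferases that use S-adenosylmethionine, 8 rose and 6 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.358), with Prmt1 (1.21) and the RNA methyltransferase Nsun2 (1.19) higher. Of 22 senescence and p53 genes, 4 rose and 4 fell (5 and 4 adjusted over the list alone, median 0.26, camera adjusted p = 0.579, with fry pointing down). The cell-cycle inhibitor Cdkn1a rose from 86.3 ± 4.09 to 316 ± 141 CPM (1.87, SE 0.33, edgeR adjusted p = 0.0184), and the inhibitor Cdkn2b (-1.48), Gadd45g (-1.04) and Sesn1 (-0.81) fell.

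**Figure D3:**
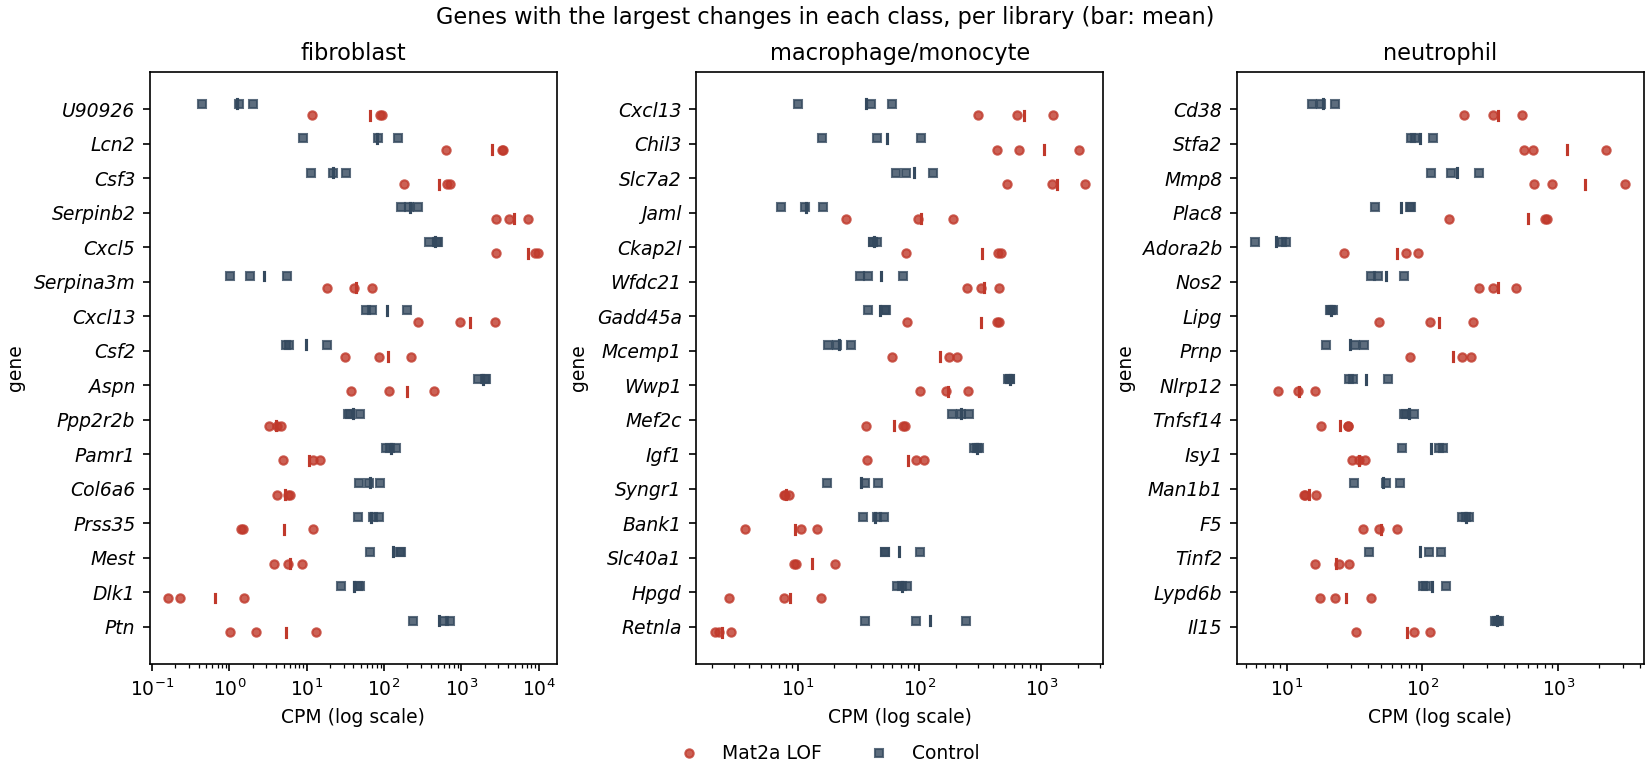
CPM (horizontal axis, log scale) of the genes with the largest called changes, among those with at least 20 CPM and 10% of their CPM in the highest class and predicted and immunoglobulin genes passed over, in fibroblasts, macrophages and neutrophils, with 1 point per library (red circles Mat2a LOF, dark squares control) and a bar at the mean. In fibroblasts Lcn2 averages 2464 CPM in LOF and 81.6 CPM in control, and Ptn 5.44 and 510 CPM.

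Macrophages of the LOF libraries carried more RNA for Cxcl13, Slc7a2 and Ldha and less for Retnla, Hpgd and Igf1. Cluster 2, led by Chil3, Ms4a4c and Ccl5, held 36.5%, 78.6% and 71.6% of macrophages in LOF 1, 2 and 3 and 36.7 ± 10.4% in control, so LOF 1 lay within the control range. Cluster 7, led by Ppbp, Pf4 and Arg1, held 48.2%, 18.5% and 14.7% in LOF and 37.9 ± 13.7% in control, and cluster 14, led by Cd209f, Clec10a and Folr2, 10.6 ± 6.75% and 25.4 ± 3.74%. Fold changes of the macrophage sums include these shifts, and changes within a single cluster were not tested. edgeR called 886 of 14811 genes, 462 higher and 424 lower (3123 in the males alone, 816 of them shared). 36.9% of genes separated the groups, where chance gives 10%. The count was 4928 without LOF 1, 33 without LOF 2, 2 without LOF 3, 1 without Control 1, 4 without Control 3, and 0 without Control 2, where 3167 genes had an unadjusted edgeR p under 0.05. Of the 79 called genes that the rule picks, 79 were still called without LOF 1, 4 without LOF 2, 1 without Control 3 and 0 without LOF 3, Control 1 or Control 2. The planned block on replicate number, a number the labels do not explain, removed the call of 59 of these 79.

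The chemokine Cxcl13 rose in macrophages from 36.7 ± 25 to 726 ± 480 CPM (log2 fold change 4.30, SE 0.78, edgeR adjusted p = 0.0363), and Chil3, a chitinase-like protein, by 4.27. Of 24 genes of inflammatory macrophages, 5 rose and none fell (17 up and 1 down adjusted over the list alone, median 1.70, camera adjusted p = 6.9e-05 and 0.68 with an estimated correlation). They include the arginine carrier Slc7a2 (3.89), itaconate-making Acod1 (2.18), Nos2, from 98.3 ± 49.1 to 436 ± 138 CPM (2.15), and the receptor Clec4e (1.92). Of 35 NF-kB targets, 6 rose and none fell (31 and 1 adjusted over the list alone, median 1.21, camera adjusted p = 2.6e-09 and 0.68 with an estimated correlation), with Sod2 (1.77), Irak3 (1.28) and Tnip1 (1.18), the last a brake on NF-kB. Of 23 glycolysis genes, 13 rose and none fell (17 and 0 adjusted over the list alone, median 0.91, camera adjusted p = 2.6e-08 and 0.239 with an estimated correlation). Ldha rose from 211 ± 11.8 to 506 ± 48.7 CPM (1.26, SE 0.14, edgeR adjusted p = 0.0179), with Eno1 (1.20), Pgk1 (1.12) and Pfkl (0.95). Of 25 hypoxia targets, 5 rose and none fell (15 and 0 adjusted over the list alone, camera adjusted p = 3.8e-07 and 0.33 with an estimated correlation), among them Bnip3 (1.09), Slc2a1 (1.03) and Ddit4 (1.02).

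Of 65 secretory genes associated with senescence in macrophages, 6 rose and 3 fell (20 and 6 adjusted over the list alone, camera adjusted p = 0.0408 and 0.68 with an estimated correlation). The urokinase receptor Plaur (1.71) and the TNF receptor Tnfrsf1b (1.06) rose, and Igfbp4 (-1.49) and Il15 (-1.28) fell. Without LOF 2, LOF 3, Control 1 or Control 2, camera no longer called this list (adjusted p = 0.193, 0.0904, 0.0692 and 0.0811). Of 25 antioxidant genes, 3 rose and none fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0188 and 0.68 with an estimated correlation), with the cystine carrier Slc7a11 (1.23) and glutathione reductase Gsr (1.00). The camera call was lost without LOF 1 (adjusted p = 0.295) and Control 3 (0.138). Of 20 senescence and p53 genes, Gadd45a rose (2.74), Sesn1 fell (-1.07) and 18 were not called (5 up and 3 down adjusted over the list alone, camera adjusted p = 0.387). Of 48 proliferation genes, Mki67 rose (1.49), Cenpa fell (-1.45) and 46 were not called (1 and 1 adjusted over the list alone, camera adjusted p = 0.495). In the methionine cycle, 1 of 21 genes was called, methionine synthase Mtr (-0.70), and among 38 methyltransferases Kmt5a rose (1.22) and Dnmt3a fell (-0.95) (camera adjusted p = 0.387 for both lists).

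Of 9 genes of MHC class II presentation, 5 fell and none rose in macrophages (6 down and 1 up adjusted over the list alone, median log2 fold change -1.16, camera adjusted p = 0.000511 and 0.56 with an estimated correlation, 0.0794 without LOF 1). H2-DMb1, which helps load peptides, fell by 1.05 at 0.109 of its CPM in the highest class. The regulator Ciita (-2.53), H2-Eb1 (-1.90) and H2-Aa (-1.80) lie at 0.052, 0.075 and 0.085 of theirs. Of 25 genes of reparative macrophages, 7 fell and 1 rose (10 and 3 adjusted over the list alone, median -0.55, camera adjusted p = 0.00603 and 0.68 with an estimated correlation). Retnla fell from 123 ± 105 to 2.40 ± 0.407 CPM (-5.67, SE 0.74, edgeR adjusted p = 0.0268), Igf1 from 295 ± 13.6 to 79.9 ± 37.9 CPM (-1.89), and Pdgfc (-1.60) and Ccl24 (-1.3) fell too. The riser is Chil3. Unnamed cluster 6, led by Stab1, Mrc1 and Cd163 of this list, is not in these counts. Beyond the lists, the prostaglandin-degrading Hpgd (-3.04), the iron exporter Slc40a1 (-2.39), Bank1 (-2.17) and the transcription factor Mef2c (-1.83) fell. Of 50 matrix genes, 6 fell in macrophages (30 down and 5 up adjusted over the list alone, camera adjusted p = 4.7e-06 and 0.68 with an estimated correlation), but the 43 members under 10% of their highest class had a median of -1.40 and the others 0.80.

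Neutrophil cluster 0, led by F5, Il15 and Cxcr2, held 89.1 ± 3.1% of control and 8.17 ± 1.74% of LOF neutrophils. The LOF libraries differed in where the rest lay. Cluster 4, led by Ngp, Cd177 and Mmp8, held 72.0% and 71.4% of neutrophils in LOF 1 and 2 but 2.52% in LOF 3, against 1.23 ± 0.713% in control. Cluster 3, led by Il23a and Ccl3, held 55.1% in LOF 3 but 11.3% and 7.08% in LOF 1 and 2, against 7.11 ± 1.9% in control, and cluster 8, led by Slfn4 and G0s2, 18.7 ± 12.8% in LOF and 2.53 ± 0.947% in control. LOF neutrophils carried more RNA for Cd38, Stfa2 and Mmp8 and less for Il15, F5 and Cxcr4, on counts scaled to the library. Stfa2 and Mmp8 are among the leading genes of cluster 4, and Il15 and F5 of cluster 0. Their fold changes include the shift between clusters, and changes within a single cluster were not tested. The median UMI count per neutrophil was 5160, 5553 and 7137 in LOF 1, 2 and 3. In Control 1, 2 and 3 it was 3968, 3034 and 4195, so depth per neutrophil runs with group. edgeR called 396 of 12466 genes, 166 higher and 230 lower (468 in the males alone, 252 of them shared). 195 of the 396 lie at 10% or more of their CPM in the highest class, and 23.6% of genes separated the groups, where chance gives 10%. The count was 701 without LOF 1, 219 without LOF 2, 885 without LOF 3, 127 without Control 1, 12 without Control 2 and 22 without Control 3. Of the 43 called genes that the rule picks, 41, 28, 39, 16, 5 and 5 were still called. The planned block on replicate number, a number the labels do not explain, removed the call of 39 of these 43.

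Among called neutrophil genes with at least 20 CPM and 10% of their CPM in the highest class, predicted genes passed over, the ectoenzyme Cd38 rose most, from 18.7 ± 3.87 to 360 ± 173 CPM (log2 fold change 4.26, SE 0.39, edgeR adjusted p = 0.00214), with rises too in Stfa2 (3.57), the collagenase Mmp8 (3.11), Plac8 (3.09), the adenosine receptor Adora2b (2.93), Lipg (2.64) and the prion protein gene Prnp (2.51). Of 24 hypoxia targets, 4 rose and none fell (8 and 0 adjusted over the list alone, median 0.67, camera adjusted p = 1.1e-05 and 0.799 with an estimated correlation). They are the oxygen sensor Egln1 (1.67), the oxidase Ero1a (1.65), the lipid droplet gene Hilpda (1.64) and Bnip3 (1.3). Of 23 glycolysis genes, Gpi1 rose (1.57), none fell and 22 were not called (12 up and 1 down adjusted over the list alone, camera adjusted p = 9.5e-05 and 0.799 with an estimated correlation). Of 23 genes of inflammatory macrophages, 3 rose (4 adjusted over the list alone, camera adjusted p = 0.0154 and 0.799 with an estimated correlation), with Nos2 from 54.3 ± 17.1 to 360 ± 114 CPM (2.72, SE 0.32, edgeR adjusted p = 0.0049) and Ly6c2 (2.38). No NF-kB target was called over all genes, 2 of 35 rose adjusted over the list alone, and the median was 0.54 (camera adjusted p = 0.0363 and 0.799 with an estimated correlation). With genes under 10% of their CPM in the highest class left out, camera still called the hypoxia list (adjusted p = 0.00107, 2.8e-08 to 0.799 over its alternatives) and the glycolysis list (0.0019, 1.4e-06 to 0.799). It no longer called the inflammatory list (adjusted p = 0.286, 5.8e-05 to 0.799 over its alternatives) or the NF-kB list (0.419, 7.9e-05 to 0.853). Their medians were then 0.56 and 0.51, so the NF-kB median stayed near 0.54 while fewer genes were tested. With all genes in, camera called neither of these 2 lists without LOF 3 (adjusted p = 0.632 and 0.853) or Control 2 (0.148 and 0.133).

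The cytokine Il15 fell in neutrophils from 353 ± 11.5 to 77.5 ± 41.3 CPM (log2 fold change -2.19, SE 0.40, edgeR adjusted p = 0.023), with Lypd6b (-2.11), the telomere gene Tinf2 (-2.06), coagulation factor F5 (-2.06), Man1b1 (-1.83), Isy1 (-1.76), Tnfsf14 (-1.67), Nlrp12 (-1.64) and the marrow-homing receptor Cxcr4 (-1.38). Of 64 secretory genes associated with senescence, 3 rose and 3 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.355). Ptges, which makes prostaglandin E, rose by 1.70. No gene was called by edgeR among 14 of the methionine cycle (median -0.23, 1 up and 1 down adjusted over the list alone), 43 of proliferation (median 0.11, 0 and 0) or 19 of senescence and p53 (median -0.00084, 0 and 0). Of 45 interferon genes none was called (0 and 0 adjusted over the list alone). The median was 0.37 while camera pointed down (adjusted p = 0.777). Of 50 matrix genes, 11 fell and none rose (31 down adjusted over the list alone, camera adjusted p = 5.2e-17 and 0.716 with an estimated correlation), among them Eln (-3.40), Col14a1 (-3.38) and Lum (-1.92). All 3 lie under 10% of their CPM in the highest class, the 45 such members had a median of -1.66, and the others 0.28.

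Keratinocytes, endothelial cells and lymphocytes gave few calls. In keratinocytes edgeR called 1 of 14058 genes, Eln (29.2 ± 1.48 to 2.72 ± 0.792 CPM, log2 fold change -3.40, adjusted p = 0.0362), which lies at 0.055 of its CPM in the highest class. 1068 genes had an unadjusted p under 0.05 and DESeq2 called 271. The males alone gave 13, and leaving out any 1 of the 6 libraries gave 0, with 652 (without LOF 2) to 2168 (without Control 3) genes at an unadjusted p under 0.05. Clusters 9 and 15 held 58.6% and 37.3% of LOF keratinocytes and 47.0% and 46.4% of control ones. The 21 methionine cycle genes had a median log2 fold change of 0.18 with none called (1 adjusted over the list alone, camera adjusted p = 0.0198 and 0.709 with an estimated correlation, 0.0771 without LOF 1, 0.0796 without LOF 2 and 0.0872 without Control 3). The 25 hair follicle genes had a median log2 fold change of -0.75 with none called (0 adjusted over the list alone, camera adjusted p = 0.000211 and 0.709 with an estimated correlation). The 36 keratinocyte differentiation genes had a median of -0.33 (none called, 0 adjusted over the list alone, camera adjusted p = 0.0418 and 0.75 with an estimated correlation, 0.532 without LOF 2, 0.0561 without Control 1 and 0.296 without Control 2). The 30 genes of wound-edge keratinocytes had a median of -0.07, a mean of 0.13 and a camera call upward (none called, 0 adjusted over the list alone, adjusted p = 0.000551 and 0.709 with an estimated correlation, 0.223 without Control 1).

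In endothelial cells edgeR called 0 of 12039 genes. 1587 had an unadjusted p under 0.05 and DESeq2 called 202. The males alone gave 44, leaving out LOF 1 gave 133 and leaving out LOF 2 gave 19. LOF 2 held only 57 endothelial cells, against 427 to 783 in the other libraries, so few calls are no evidence of little change. Among the genes nearest to the threshold, none of which passed, Tmem252 had a log2 fold change of 1.32 (664 ± 62.8 against 266 ± 9.68 CPM, edgeR adjusted p = 0.0868, higher in each LOF library), the zinc carrier Slc39a14 1.26, Nhp2 1.08 and Qsox1 0.79, and Nalf1 -3.07, Nrep -1.68, Map2k6 -1.21 and Col8a1 -0.93. The 21 glycolysis genes had a median of 0.86 (none called, 11 up and 0 down adjusted over the list alone, camera adjusted p = 2.0e-05 and 0.472 with an estimated correlation), and the 20 genes of the unfolded protein response 0.73 (none called, 0 adjusted over the list alone, camera adjusted p = 8.8e-06 and 0.472 with an estimated correlation). The 31 angiogenesis genes had a median of 4.4e-05 and a mean of -0.02 (none called, 0 adjusted over the list alone, camera adjusted p = 0.983).

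In lymphocytes edgeR called 12 of 9711 genes, 1 higher and 11 lower (168 in the males alone, 12 of them shared). 1232 had an unadjusted p under 0.05 and DESeq2 called 143. LOF 1 held only 61 lymphocytes, against 175 to 881 in the other libraries, so few calls are no evidence of little change. The N-myristoyltransferase gene Nmt2 fell from 237 ± 39.2 to 93.4 ± 9.76 CPM (log2 fold change -1.36, edgeR adjusted p = 0.0479) and the transcription factor gene Eya1 by 1.71, each lower in 3 of 3 LOF libraries. Csf3 (4.38), Col14a1 (-4.31) and Aspn (-5.45) were called at 0.029, 0.037 and 0.040 of their CPM in the highest class. The count was 468 without LOF 1, 3 without Control 1, and 0 without LOF 2, LOF 3, Control 2 or Control 3, where 656, 696, 742 and 1548 genes had an unadjusted edgeR p under 0.05. Of 34 NF-kB targets 1 rose, Csf3 (4 up and 0 down adjusted over the list alone, median 0.40, camera adjusted p = 0.000552 and 0.475 with an estimated correlation, 0.0759 without LOF 1). With genes under 10% of their CPM in the highest class left out, camera no longer called these NF-kB targets (adjusted p = 0.201, 1.1e-05 to 0.475 over its alternatives). The 5 genes of MHC class II presentation had a median of -1.31 (none called, 3 down adjusted over the list alone, camera adjusted p = 0.00639 and 0.475 with an estimated correlation). Free RNA of other cells as the source of these class II counts stays open.

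**Figure D4:**
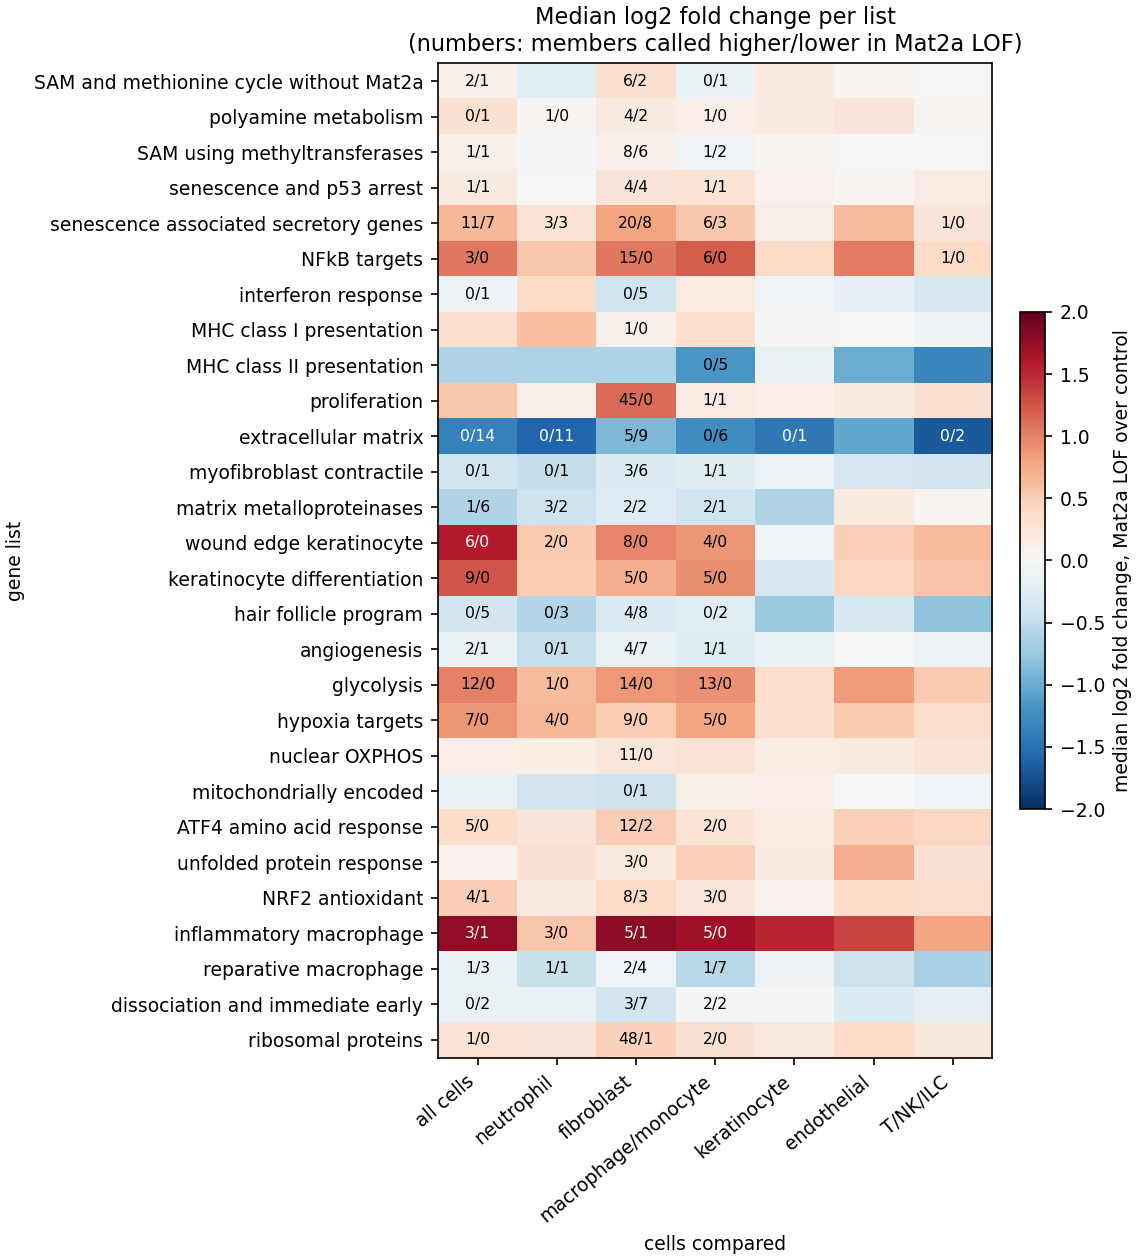
Median log2 fold change of Mat2a LOF over control (colour) for 28 gene lists (vertical) in all cells and 6 classes (horizontal), with the numbers of members called higher and lower printed in each field that has any. Proliferation reads 45/0 in fibroblasts and 1/1 in macrophages, and glycolysis 14/0 and 13/0.

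Of the 28 lists, camera called 11 in all cells, 12 in neutrophils, 15 in fibroblasts, 16 in macrophages, 15 in keratinocytes, 17 in endothelial cells and 17 in lymphocytes. In the males alone it called 12, 14, 10, 15, 13, 16 and 13. With an estimated correlation it called 0 of 28 in each of the 7 comparisons, and fry called 4 in all cells, 7 in fibroblasts, 4 in macrophages and 0 in the other classes.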

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

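The tests of whether classes changed differently, and the tests on fibroblast proliferation genes, were chosen only after the results were seen; the splits of the libraries were planned.

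Classes changed by different amounts in edgeR's test of the interaction of class and group. Between fibroblasts and neutrophils 471 of 18819 genes differed in their log2 fold change, 255 with a higher and 216 with a lower value in fibroblasts. Of the 471, 230 lie at 10% or more of their highest class in both. Tested alone, 12466 genes passed the low-count filter in neutrophils and 14811 in macrophages. Some genes in these interaction tests therefore fall under that filter in 1 of the classes. Isy1 (difference 2.52, SE 0.32, edgeR adjusted p = 0.00063) and Rrp1b (2.49) were higher and Prnp (-3.48) lower in fibroblasts; these genes were chosen after their values were seen. Between fibroblasts and macrophages 381 of 17556 genes differed, 261 higher and 120 lower, among them the centromere gene Cenpa (2.48, SE 0.19, edgeR adjusted p = 0.0127), the transferrin receptor Tfrc (3.49) and Slc7a2 (-2.65). Between macrophages and neutrophils 266 of 15480 genes differed, 172 higher and 94 lower, with Cd38 (-2.94, SE 0.31, edgeR adjusted p = 0.00118), F5 (2.37) and Tnfsf14 (2.36). Taken gene by gene, the difference of fibroblasts from neutrophils had a median of 0.74 over NF-kB targets (camera adjusted p = 2.4e-05, 0.834 with an estimated correlation). Macrophages differed from neutrophils by a median of 0.65 over these targets (camera adjusted p = 3.3e-06, 0.977 with an estimated correlation). Fibroblasts differed from macrophages by -0.025 (camera adjusted p = 0.903), so by median the NF-kB difference lay between neutrophils and both other classes. Over MHC class II genes the difference of macrophages from neutrophils had a median of -0.71 (camera adjusted p = 0.000771, 0.885 with an estimated correlation). In macrophages Ciita, H2-Eb1 and H2-Aa lie under 10% of their CPM in the highest class. Free RNA of other cells as a source of this difference stays open. Over methionine cycle genes the difference of fibroblasts had a median of 0.50 from neutrophils (camera adjusted p = 0.00962, 0.543 with an estimated correlation). From macrophages it was 0.48 (camera adjusted p = 0.0274, 0.954 with an estimated correlation). These tests took 22 members, more than passed the low-count filter in neutrophils or macrophages alone, so some are little counted there.

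Libraries decide the size of these counts. The 471 became 1063 without LOF 1, 219 without LOF 2, 789 without LOF 3, 208 without Control 1 and 21 without Control 2. The 381 became 3570 without LOF 1, 10 without LOF 2, 15 without LOF 3 and 0 without Control 1, Control 2 or Control 3 by edgeR, where the unadjusted count was not kept and DESeq2 was not run; with all libraries 4094 genes had an unadjusted p under 0.05. The 266 became 712 without LOF 1, 142 without LOF 2, 3 without Control 1, 21 without Control 2 and 48 without Control 3. In the males alone the counts were 860, 2024 and 289, and with no filter on low counts 1139, 493 and 967. The balance moved too. Between fibroblasts and macrophages it was 190 higher and 132 lower with DESeq2 size factors. It was 248 and 245 with no filter on low counts, and 931 and 1093 in the males alone. Between fibroblasts and neutrophils DESeq2 size factors gave 388 higher and 193 lower. The 10 splits of the 6 libraries into 3 and 3 cannot give a share under 0.05; the real counts are 471, 381 and 266, the highest of the other splits is 0 for each, and 1 split, the real one, gives a result as large.

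With all libraries 45 of 48 proliferation genes were called higher in LOF fibroblasts (camera adjusted p = 2.0e-17; 0.521 with an estimated correlation). Without Control 1 or Control 2 edgeR called only 25 and 34 fibroblast genes of any kind. Free RNA of dividing cells of other classes would raise the list about as much in neutrophils and macrophages. The group difference of its mean log2 CPM was larger in fibroblasts than in neutrophils by 0.99 (SD 0.25). It was larger than in macrophages by 0.97 (SD 0.11), which argues against that source alone. The called members of each class were known when this test was chosen, so its direction was known beforehand. A larger share of the dividing cells of cluster 20 stays open: without that cluster 18 members were called and the median log2 fold change went from 1.13 to 0.68, between the bounds set for the test. Whether Mat2a alteration itself raised division is among the open explanations, as untested, since division was not measured apart from RNA.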

How the results depend on the processing

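Sex as a covariate, the male libraries alone, the return of unnamed clusters and fibroblasts without cluster 20 were chosen only after the results were seen; the other alternatives were planned. Counts are genes called by edgeR, or lists called by camera, unless another tool is named; lists and Mat2a are given as log2 fold changes, and the cause of a change was not tested unless stated.

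DESeq2 size factors left all 15 main results on their side, and the stricter cell filter all 16. DESeq2's own test called 4834 genes in all cells, 915 in neutrophils, 2510 in macrophages, 271 in keratinocytes, 202 in endothelial cells and 143 in lymphocytes. In simulation with 200 changed genes, 12.6% to 41.1% of its calls were unchanged genes. That share depends on how many genes change, so it need not hold for these counts. Mat2a in lymphocytes was 0.012 by DESeq2's own test. With no filter on low counts 1326 genes were called in neutrophils, 29 in keratinocytes, 72 in endothelial cells and 630 in lymphocytes, and Mat2a was -0.00019 in fibroblasts, 0.032 in keratinocytes and 0.0071 in lymphocytes. With no doublet removal 4 genes were called in keratinocytes and 10 lists in lymphocytes; Mat2a was 0.031 in keratinocytes and 0.40 in lymphocytes, where the medians were 0.026 for the methionine cycle, 0.052 for interferon genes, -0.031 for oxidative phosphorylation, 0.020 for ATF4 genes, 0.0087 for dissociation genes and -0.014 for genes with ribosomal symbols, S6 kinase genes included. The stricter filter gave 0.057 for the methionine cycle in endothelial cells. Permutation of the shares cannot give a p under 0.1, so it could call none. edgeR on cell counts, which could, called none. Fibroblasts had a log2 fold change of -1.14 there (edgeR unadjusted p = 0.105, adjusted p = 0.466). The centred log-ratio gave 0.12 for skeletal muscle. Leiden resolution 0.5 gave a dendritic difference of 0.068 percentage points. Only 20 cells, all of LOF 1, took the dendritic name there, so this is not the set of cells of the main clustering. A cluster of 1205 cells with Ccr7 and Flt3 among its top genes stayed unnamed at that resolution.

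Leaving out genes under 10% of their highest class, which tests fewer genes, called 152 genes in neutrophils, 526 in macrophages and by edgeR 0 in keratinocytes and 0 in lymphocytes (509 and 929 at an unadjusted p under 0.05; DESeq2 was not run there), and 3 lists in neutrophils, 11 in endothelial cells and 8 in lymphocytes. Matrix medians became 0.28 in neutrophils, 0.80 in macrophages (camera adjusted p = 0.00325; 7.5e-09 to 0.68 over its alternatives), 0.11 in keratinocytes and 0.33 in lymphocytes; contractile genes were 0.29 in neutrophils, metalloproteinases 0.55 in keratinocytes (camera adjusted p = 0.0354; 0.00206 to 0.783 over its alternatives), the methionine cycle 0.070 in endothelial cells and 0.0029 in lymphocytes, and in lymphocytes secretory genes 0.043 and inflammatory genes -0.45. An estimated correlation called 0 lists in each of the 7 comparisons; fry called 4 in all cells, 7 in fibroblasts, 4 in macrophages and 0 in the others, and pointed against the medians of 0.26 for senescence genes in fibroblasts and 0.0029 for the methionine cycle in lymphocytes.

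Sex as a covariate gave 1062 genes in all cells and 215 in neutrophils. The males alone gave 456 in all cells, 7251 in fibroblasts, 3123 in macrophages, 13 in keratinocytes, 44 in endothelial cells and 168 in lymphocytes, and Mat2a at 0.20 in keratinocytes. No named gene that was called changed sign under an alternative.

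With the replicate number as a block (replicate block), 18 genes were called in neutrophils, 129 in macrophages, 3 in keratinocytes, 2 in endothelial cells and 33 in lymphocytes. Of the named genes that had been called, 4 of 43 stayed called in neutrophils, 20 of 79 in macrophages and 106 of 111 in fibroblasts. The labels do not say what the number marks. In all cells the libraries numbered 2 and 3 correlated best with their own number across genes (0.33 and 0.40), but LOF 1 correlated at 0.31 with Control 2 and at 0.074 with Control 1, so not every library correlates best with its own number; the libraries numbered 1 are both female.

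Leaving out 1 library in turn gave, lowest to highest, 0 to 3575 genes in all cells, 12 to 885 in neutrophils, 25 to 9095 in fibroblasts, 0 to 4928 in macrophages, 0 to 0 in keratinocytes, 0 to 133 in endothelial cells and 0 to 468 in lymphocytes, with fewer libraries to fit. Mat2a ran from -0.58 to 0.082 in neutrophils, -0.015 to 0.049 in fibroblasts, -0.23 to 0.12 in keratinocytes, -0.24 to 0.11 in endothelial cells and -0.46 to 0.29 in lymphocytes. Senescence and p53 genes ran from -0.17 to 0.12 in neutrophils, 0.043 to 0.14 in keratinocytes and 0.11 to 0.21 in lymphocytes, NF-kB targets 0.0029 to 0.73 in neutrophils, secretory genes 0.048 to 0.31 in keratinocytes, and the methionine cycle -0.043 to 0.079 in endothelial cells and -0.15 to 0.18 in lymphocytes. Differences in share ran, in percentage points, from -0.11 to 0.64 for adipocytes, -0.79 to 0.019 for dendritic cells, -0.34 to 0.038 for muscle satellite cells, -0.54 to 2.95 for lymphocytes, -1.18 to 0.23 for pericytes and -0.062 to 0.096 for lymphatic cells.

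The 10 splits of the libraries cannot give a share under 0.05. For genes, the real count and the highest other were 1869 and 0 in all cells, 396 and 0 in neutrophils, 4471 and 0 in fibroblasts, 886 and 0 in macrophages (1 split as large in each), 0 and 0 in endothelial cells (10 splits), 1 and 70 in keratinocytes and 12 and 234 in lymphocytes (2 splits each). The last 2 come from LOF 1, Control 1 and Control 2 against the rest, which points to a structure of the samples; both female libraries lie on the same side of that split, so a part of sex in it stays open. For lists they were 11 and 18 in all cells (7 splits), 12 and 15 in neutrophils (5), 15 and 12 in fibroblasts (1), 16 and 16 in macrophages (2), 15 and 16 in keratinocytes (4), 17 and 13 in endothelial cells (1) and 17 and 12 in lymphocytes (1).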

Other observations

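The tests on Mat2a RNA were chosen only after the results were seen; the test on free RNA of fibroblasts was planned.

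Of 30 wound-edge keratinocyte genes, 8 rose and none fell in fibroblasts (11 and 0 adjusted over the list alone; camera adjusted p = 9.5e-06; 0.521 with an estimated correlation), among them the fibronectin receptor subunit Itga5 (1.02) and the transcription factor Fosl1 (1.18); Areg (2.44) and Plaur (1.64) lie at 0.069 and 0.066 of their CPM in the highest class. Of 33 angiogenesis genes in fibroblasts, 4 rose and 7 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.403): the peptide hormone gene Apln rose by 2.50 and the receptor gene Tek fell by 2.11. Of 25 antioxidant genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0847), with ferritin Fth1 (1.78) higher and Gstm1 (-0.82) lower. Of 25 keratinocyte differentiation genes in macrophages, 5 rose (7 adjusted over the list alone; camera adjusted p = 3.3e-06; 0.239 with an estimated correlation); Krt1 (1.92) and Asprv1 (2.25) lie at 0.0096 and 0.015 of their CPM in the highest class.

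camera called the matrix list lower in LOF in the 5 tested classes other than fibroblasts, though edgeR called 11 of 50 members in neutrophils, 6 of 50 in macrophages, 1 of 50 in keratinocytes, 0 of 47 in endothelial cells and 2 of 43 in lymphocytes. With an estimated correlation none of these calls held (adjusted p = 0.716, 0.68, 0.709, 0.472 and 0.475). A candidate source is free RNA of fibroblasts, whose share averaged 14.1% in LOF and 31.2% in control libraries, a difference not called (exact two-sided p = 0.10, the lowest possible with 3 against 3). Across genes at under 10% of their CPM in the highest class, the log2 fold change in the class followed that in all cells, as this source needs. Slopes were 0.809 in neutrophils, 0.765 in macrophages, 0.816 in keratinocytes, 0.752 in endothelial cells and 0.843 in lymphocytes. Genes are not independent replicates. The fit took genes of any highest class, and only 438 of 4703 in neutrophils and 162 of 972 in lymphocytes are highest in fibroblasts. All cells also include the class itself, so a slope is partly built in. The slopes therefore do not single out fibroblasts as the source. Genes highest in fibroblasts had median log2 fold changes of -0.99 in neutrophils and -1.26 in lymphocytes, against -0.85 and -0.96 in all cells. In the 5 classes in that order, matrix members under the 10% bound had medians of -1.66, -1.40, -1.82, -1.70 and -1.82. The others had 0.28, 0.80, 0.11, -0.19 and 0.33. A change of matrix genes within these classes stays possible. A fall shared by several classes would give such slopes too, so they do not exclude it for the members under the bound.

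Mat2a RNA was not called lower with all libraries in any class tested. The log2 ratio was 0.03 (SE 0.05) in fibroblasts, -0.05 (SE 0.22) in keratinocytes and -0.10 (SE 0.24) in endothelial cells. These values argue against a fall of counted Mat2a RNA by 1 log2 unit in those classes. In some smaller classes the spread may hide such a loss. The lowest log2 ratio over named classes was -0.83 (SE 0.47) in adipocytes, which reaches neither a fall of 1 log2 unit nor excludes it. Pericytes and smooth muscle had -0.77 (SE 0.23) and skeletal muscle -0.69 (SE 0.35). An altered part of the gene outside the counted 3′ ends could leave the counts near those of control, and the log2 fold change over all cells of -0.26 (SE 0.14) does not decide between that and a small fall. The labels name neither the part nor the cells, so these cannot be told apart.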
